A study of Mus musculus with 18 samples.

How the data were processed

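Liver RNA of male mice was measured on 18 Affymetrix Mouse430_2 arrays, which hold 45101 probe sets. The arrays form 6 groups of 3: wild-type (Hmgn1+/+) and knockout (Hmgn1-/-) livers, each from animals that were not injected at 4 weeks, injected with saline, or injected with N-nitrosodiethylamine (DEN), a carcinogen that liver enzymes activate. DEN was given at 10 µg per g of body weight at 4 weeks of age. The labels give 12 weeks for the injected groups; the series text reads as 12 weeks after the injection, the sample titles do not say from when the weeks are counted, and the age at collection is therefore uncertain. The 2 genotypes were propagated as separate homozygous lines, so a difference between them can come from the targeted gene or from anything else in which the lines differ. The labels do not say that the 3 arrays of a group come from 3 animals, so the p-values measure the spread between these samples.

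The deposited values are intensity values on a linear scale, 1 per probe set and array. Per the submitters' processing notes they were made with MAS5, whose version is not given, and scaled to a common trimmed mean; recomputed without the lowest and highest 2 percent of probe sets, the mean was 150 on each array. No raw image data were used, and no count or depth exists for an array; the number of arrays limits the precision. From these values, 64 control probe sets were set aside, 16 was added, and log2 was taken. Probe sets whose mean log2 value over the 18 arrays was at or above the 40th percentile were tested, which left 27022. Of the 45037 probe sets that are not controls, 34945 map to a single gene in the platform annotation, 932 to several and 9160 to none. Where each gene counts once, it is represented by its tested probe set with the highest mean, which gave 12896 genes. Gene positions are those of build GRCm38.

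Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 1 coefficient per group and a shared spread from 12 residual degrees of freedom and a prior of 9.19. All tests were two-sided, and adjusted p-values are limma p-values after the Benjamini-Hochberg correction over the tested probe sets of a contrast, with a threshold of 0.05. "Rose" and "fell" are used for changes under that threshold. The contrasts set before the data were examined were the knockout minus wild-type difference in each condition and its mean, the DEN minus saline difference in each genotype and its mean, the saline minus 4-week difference in each genotype, and the difference of these responses between genotypes. A comparison of DEN with the 4-week arrays and of the genotype effect with DEN against that at 4 weeks were added after the data were seen. Errors given as SE are those of the fitted log2 difference (n = 3 arrays per group).

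Before the data were examined, 39 gene lists for liver pathways, cell types and neighbouring tissues were also fixed, with 767 genes, of which 616 were measured. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Of 121 list calls over the 11 planned contrasts, 25 held with an estimated correlation, all of them in comparisons of the saline arrays with others. With quantile-normalized values, camera with an estimated correlation called 0 lists in these contrasts. Counts of list members are given over all tested probe sets and adjusted over the list alone.

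The rule for naming genes was also set then. It took Hmgn1, the 10 largest rises and 10 largest falls per contrast among genes with an adjusted p under 0.05 (or, where none passed, the 3 smallest p-values in each direction), up to 4 members of each called list, the HMG family, Cyp2e1, Afp, and called neighbours of Hmgn1 on chromosome 16. This named 285 genes. The gene values that are discussed and followed through the alternatives were narrowed after the data were seen: list members were kept only where their list was also called with quantile-normalized values, because many highly expressed members of the other lists changed sign with the normalization. The effect of the alternatives over all gene values of the original rule is given with that over the narrowed set.

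Alternatives planned before the data were examined were quantile normalization, centring the array medians, adding 1 or 64 in place of 16, no filter or a filter at the 60th percentile, no intensity trend, array quality weights, a replicate block, leaving out probe sets with names in _x_at or _s_at, fitting the compared groups alone, the mean of all probe sets of a gene in the lists, and leaving out each array in turn. Added after the data were seen were cyclic loess normalization, the Gapdh 3' to 5' ratio as a covariate, leaving out the 4-week array with the highest such ratio in each genotype, and leaving out the 6 saline arrays. The calls were tested on simulated data of the same size in which 200 probe sets were changed: in the 4-week comparison 12.5%, 63% and 97% of them were recovered at a log2 change of 0.5, 1 and 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.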

Results

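Gene expression was measured in 18 liver samples of male mice on arrays, whose number limits the precision, with 3 for each of 6 groups. These were wild type and labelled knockout of Hmgn1, a nucleosome-binding protein of the HMG family, without injection at 4 weeks, with saline at 12 weeks and with DEN at 12 weeks. The trimmed mean was 150 on all arrays, and within a group the log2 values of different arrays correlated across probe sets with r between 0.970 and 0.988. The 6 saline arrays stood apart from the other 12. Their highest signal was 16720 to 21752, against 46967 to 60173 on the others, and their 99th percentile was 4709 to 5300, against 6010 to 6720. Hybridization controls, bacterial and phage transcripts added to the sample and absent from liver, were lower on the saline arrays by a mean of -2.59 (BioB), -2.71 (BioC), -2.54 (BioDn) and -2.42 (CreX) in log2, with no overlap in 4 of 4 controls. The saline group and this difference between the arrays cannot be told apart. In comparisons with saline, values after quantile normalization, which gives all arrays one distribution, therefore stand beside most of the deposited ones. The ratio of 3' to 5' signal of Gapdh, which rises with degraded RNA, was highest on wild-type replicate 2 at 4 weeks, at 2.19, where that of Actb was 7.28. The Gapdh ratio was 0.907 or more on all arrays, and 1.70 on knockout replicate 1 at 4 weeks.

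**Figure D1:**
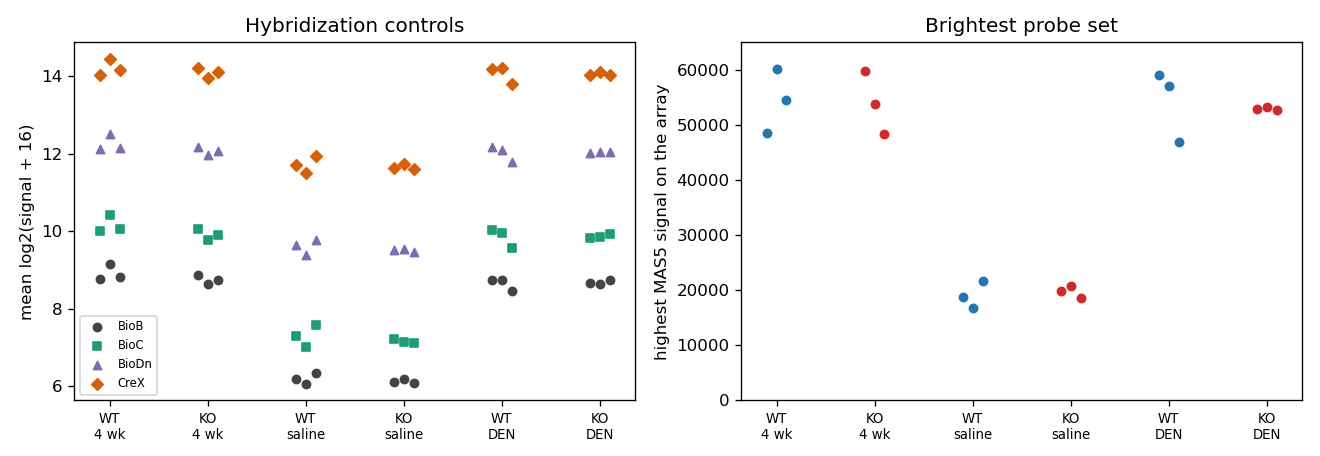
Mean log2 signal of 4 hybridization controls (left) and the highest MAS5 signal (right) on each of the 18 arrays by group, with 1 point per array. The 6 saline arrays lie below the other 12 in all 4 controls, and their highest signal is 16720 to 21752 against 46967 to 60173.

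Hmgn1 itself (chromosome 16, 96121588 to 96127725) had no called difference in signal between the labelled genotypes. At 4 weeks its probe set of highest mean had a signal of 6918 ± 947 (SD, n = 3) in wild type and 6678 ± 181 (SD, n = 3) in knockout. In the DEN group the values were 6279 ± 811 and 6309 ± 637 (SD, n = 3 each). Over 3 tested probe sets and 3 conditions the knockout minus wild-type log2 difference lay between -0.15 and 0.06, with 95% intervals that together ran from -0.35 to 0.26, and no probe set passed in any condition (adjusted p 0.577 or more). Another probe set was near the floor, at 8.82 ± 13.5 (SD, n = 3) in wild type and 16.1 ± 1.18 (SD, n = 3) in knockout at 4 weeks, and was not tested. The probe set of highest mean and another of the tested probe sets have names in _x_at, and whether they also bind other transcripts was not tested. The tested probe set with a name in _a_at differed by -0.10 at 4 weeks, -0.15 with saline and 0.06 with DEN. The sources do not say which part of the gene is deleted or where the probes lie in it, so these signals do not test the labels. The sign of the small Hmgn1 difference changed with the normalization at 4 weeks (-0.04 deposited, 0.01 quantile) and with DEN (0.01 deposited, -0.04 quantile).

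The comparison at 4 weeks asks how the livers of the 2 genotypes differ before any injection. Scara5, a scavenger receptor that binds ferritin (chromosome 14, 65666403 to 65764826), rose by 3.46 in log2 (SE 0.27, adjusted p 2.34e-07) in the knockout. Its wild-type mean was low, at 5.62 in log2 of the signal plus 16, so that the size of its difference depends on the number added. The same holds below for Slc15a2, Ezr, Spry4 and Lama5, each with a group at a low signal. Id1, an inhibitor of DNA-binding transcription factors induced by BMP signals (chromosome 2, 152736251 to 152737410), rose by 2.48 (SE 0.19, adjusted p 2.34e-07). Its relative Id3 rose by 1.37 (SE 0.13), the growth factor receptor Egfr by 1.71 (SE 0.17) and the Notch target Hes1 by 1.57 (SE 0.22). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275632), showed the largest fall among the called genes, of -2.51 (SE 0.23, adjusted p 3.49e-06). The homeobox factor Hhex, the phospholipid transfer protein Pltp and the fatty acid synthase Fasn fell by 1.57 (SE 0.17), 1.64 (SE 0.23) and 1.41 (SE 0.17). In all, 611 of 27022 probe sets changed, 343 up and 268 down, in 397 genes (230 up, 167 down). With centred array medians the split turned to 169 up and 198 down of 367.

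Genes of cholesterol synthesis were lower in the knockout at 4 weeks: 16 of 18 measured members fell and 0 rose, 17 fell adjusted over the list alone, and the median was -0.84. Examples are Lss at -1.03 (SE 0.15), Sqle, the squalene epoxidase, at -1.03 (SE 0.17), Fdft1 at -1.02 (SE 0.16) and Pmvk at -1.02 (SE 0.16). The camera test gave adjusted p = 7.15e-18, and adjusted p = 0.153 with an estimated correlation. Of 18 genes of fatty acid synthesis, 7 fell and 0 rose (10 fell adjusted over the list alone). Among them were Thrsp at -1.24 (SE 0.20), Gpam at -0.79 (SE 0.13) and Acly at -0.70 (SE 0.13). Camera gave adjusted p = 1.86e-07, and adjusted p = 0.269 with an estimated correlation. Of 15 genes with higher expression in male liver, 5 rose and 0 fell, among them Hsd3b5 at 0.70 (SE 0.12) and Cyp7b1, an oxysterol hydroxylase, at 0.75 (SE 0.12). The list test gave adjusted p = 0.000446, and adjusted p = 0.347 with an estimated correlation. Of 18 clock genes 3 rose and 0 fell (9 rose adjusted over the list alone), with Clock at 0.59 (SE 0.11). The camera test gave adjusted p = 0.00163, and adjusted p = 0.153 with an estimated correlation.

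Markers of other liver cells differed as well at 4 weeks. Of 18 macrophage and Kupffer cell genes, 5 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.48. Tyrobp, an adaptor of myeloid receptors, fell by 1.14 (SE 0.16), and Csf1r, the receptor of the macrophage growth factor, by 0.53 (SE 0.10). With camera the list had adjusted p = 1.70e-08, and adjusted p = 0.269 with an estimated correlation. Of 19 matrix and stellate cell genes 2 fell and 0 rose (6 fell adjusted over the list alone), with Dcn, the proteoglycan decorin, at -0.53 (SE 0.10). This list had camera adjusted p = 4.46e-05, and adjusted p = 0.347 with an estimated correlation. Of 29 genes of acute phase and inflammation 5 rose and 1 fell (9 rose and 2 fell adjusted over the list alone). Il1r1, the interleukin-1 receptor, rose by 1.19 (SE 0.18) and Steap4, a metalloreductase, by 0.84 (SE 0.12), while Cd14, a co-receptor for endotoxin, fell to a low signal, so that its difference of -1.25 (SE 0.26) depends on the number added. Camera gave adjusted p = 0.0134, and adjusted p = 0.535 with an estimated correlation. No member passed in the DNA repair list (34 measured, median 0.01, camera adjusted p = 0.846), the p53 target list (20 measured, median 0.08, camera adjusted p = 0.763) or the cell cycle list (22 measured, median 0.15, camera adjusted p = 0.2997), with 0 calls also adjusted over each list alone. Of 29 measured neighbours of Hmgn1 on chromosome 16, 1 rose and 1 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.691). They were the tight junction gene Cldn14 at 0.91 (adjusted p 0.0433) and the carbonyl reductase Cbr1 at -0.41 (adjusted p 0.0289). This list does not cover the whole chromosome, and other called genes lie there too. Olig1 (91269769 to 91271939) was at -1.79 (SE 0.40, adjusted p 0.0197), a call lost in 5 of 6 fits without 1 array. Slc15a2, Bcl6 and Hes1, also on chromosome 16, rose by 1.88, 1.84 and 1.57. In all, camera called 13 of 39 lists at 4 weeks, and 0 held with an estimated correlation.

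Several named calls at 4 weeks were lost without 1 array, or were not shared by other probe sets of the gene. Mt2 and Mt1, metal-binding metallothioneins, rose by 3.26 (SE 0.69, adjusted p 0.0131) and 2.79 (SE 0.58, adjusted p 0.0119), but their adjusted p became 0.0597 and 0.0585 without knockout replicate 1, with changes of 3.16 and 2.69. These calls were lost in 3 and 2 of the 6 fits without 1 array, in which the changes stayed at 3.16 to 3.42 and 2.69 to 2.91. The immediate early gene Egr1 rose by 2.03 (SE 0.50, adjusted p 0.0347), a call lost in each of these fits (adjusted p 0.117 without knockout replicate 3), with changes of 1.95 to 2.10. The call of Acta2, smooth muscle actin, at -1.35 (SE 0.35, adjusted p 0.0423) was lost in 5 of them (-0.85, adjusted p 0.157 without wild-type replicate 2, the array with the highest Gapdh ratio). Cd14 was at -0.93 (adjusted p 0.0718) without knockout replicate 1. The call of Cldn14 was lost in each of the 6 fits (0.70, adjusted p 0.143 without wild-type replicate 2) and with quantile values (0.87, adjusted p 0.0657). That of Cbr1 was lost in 4 of them (-0.35, adjusted p 0.140 without knockout replicate 3). Of the other called clock genes, Cry1, at 0.66 (SE 0.17), lost its call in 4 of these fits (0.57, adjusted p 0.177 without knockout replicate 3) and with quantile values (adjusted p 0.0604). Bhlhe40, at 0.83 (SE 0.18), lost it in 3 (0.78, adjusted p 0.0708 without wild-type replicate 3). The other tested probe set of Scara5, at a low signal, gave -0.05 (adjusted p 0.960), and both other probe sets of the peptide transporter Slc15a2, which rose by 1.88 (SE 0.28), had the opposite sign. Without the 4-week array of the highest Gapdh ratio in each genotype 180 probe sets changed, and without wild-type replicate 3 at 4 weeks 269.

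**Figure D2:**
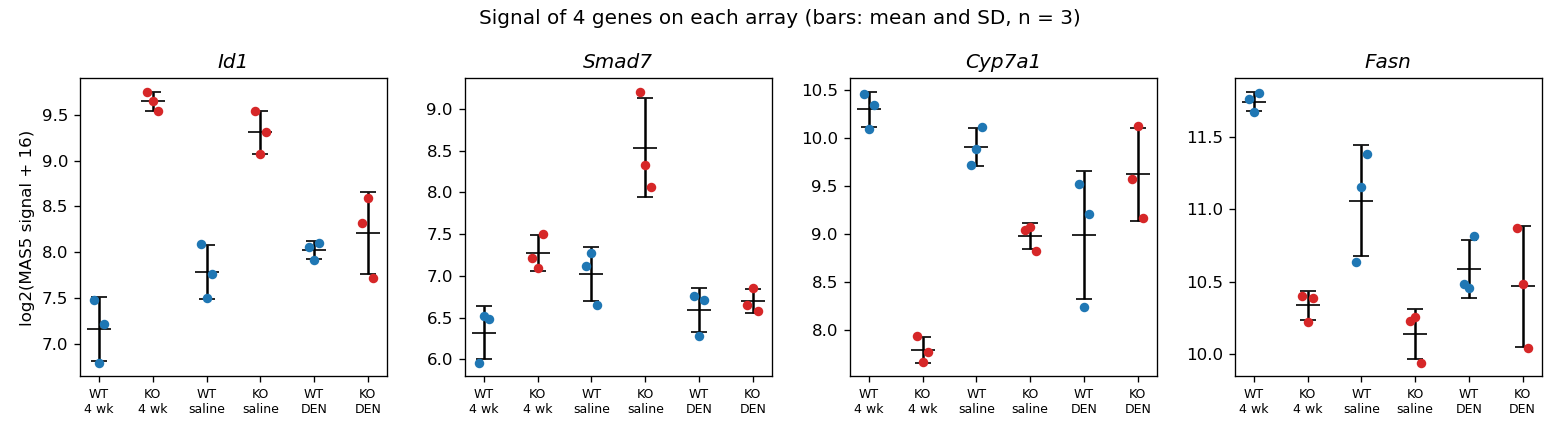
Signal of Id1, Smad7, Cyp7a1 and Fasn on each array, as log2 of the MAS5 signal plus 16, by genotype and condition, with points for arrays and bars for mean and SD (n = 3). Id1 was higher in the knockout at 4 weeks by 2.48 and with saline by 1.52, and Cyp7a1 was lower at 4 weeks by a difference of -2.51.

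With saline at 12 weeks, the same comparison of genotypes gave 3 called probe sets. Id1 rose by 1.52 (SE 0.19, adjusted p 0.00256) in the knockout and Smad7, an inhibitor in the TGF-beta pathway (chromosome 18, 75367365 to 75395935), by 1.52 (SE 0.23, adjusted p 0.0168). The third, chosen for naming after its value was seen, was Mvd, an enzyme of cholesterol synthesis, at -1.15 (SE 0.16, adjusted p 0.00392). At an unadjusted p under 0.05 there were 1426, where a share of 0.05 of the 27022 tested would pass without any difference. The same share applies to such counts below. At their probe sets of highest mean, which leaves out the called one of Mvd, all 18 cholesterol synthesis genes had negative differences, with a median of -0.39. Of these, 0 passed limma with the Benjamini-Hochberg correction over all probe sets and 6 fell adjusted over the list alone. The list test gave adjusted p = 1.43e-11, and adjusted p = 0.555 with an estimated correlation. For fatty acid synthesis the median was -0.20 (0 called, 5 lower adjusted over the list alone), camera adjusted p = 6.40e-06 and adjusted p = 0.758 with an estimated correlation. For macrophages and Kupffer cells it was -0.20 (0 called, 1 lower adjusted over the list alone), camera adjusted p = 6.39e-05 and adjusted p = 0.801 with an estimated correlation. For 14 heat shock genes the median was -0.13 (0 called, 0 adjusted over the list alone), camera adjusted p = 0.00512 and adjusted p = 0.801 with an estimated correlation. The other probe sets gave 0.80 for Smad7 (adjusted p 0.0728) and -0.41 for Mvd (adjusted p 0.941), and centring the array medians moved the median over all probe sets from 0.04 to -0.09. Without knockout replicate 1, limma called 0 probe sets (1160 at an unadjusted p under 0.05), with Id1 at 1.40 (adjusted p 0.0510) and Smad7 at 1.18 (adjusted p 0.133), and without wild-type replicate 3 Smad7 was at 1.34 (adjusted p 0.319).

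With DEN at 12 weeks, the comparison asks whether the genotypes differ after the carcinogen. Ngfr, the low-affinity nerve growth factor receptor (chromosome 11, 95568818 to 95587698), fell in the knockout (adjusted p 0.00733). Its knockout mean was 4.41 in log2 of the signal plus 16, near the floor, so that the size of the difference depends on the number added. It was -1.66 (SE 0.22) with 16 added, larger with 1 and smaller with 64. The other called probe set, chosen for naming after its value was seen, was that of Syvn1, a ubiquitin ligase of endoplasmic reticulum quality control, at -0.82 (SE 0.13, adjusted p 0.0354), against 0.54 (adjusted p 0.0296) at 4 weeks. Its other probe set gave -0.49 (adjusted p 0.388) with DEN. These 2 probe sets passed, with 2424 at an unadjusted p under 0.05. Without wild-type replicate 2 of the DEN group Ngfr was at -1.497 (adjusted p 0.141), and limma called 0 (2127 at an unadjusted p under 0.05). It called 0 as well when the DEN arrays were fitted alone (1334, Ngfr adjusted p 0.740) and without the 6 saline arrays (1642, Ngfr adjusted p 0.0579).

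The 6 measured HMG family members had positive differences with DEN, median 0.49. One of them is Hmgn1 itself, whose difference of 0.01 (SE 0.10) was -0.04 with quantile values. The others were Hmgn3 at 0.65 (SE 0.33, adjusted p 0.577), Hmgb3 at 0.57 (SE 0.19, adjusted p 0.395), Hmga2, whose signal was low, at 0.54 (SE 0.23, adjusted p 0.517), Hmgb2 at 0.43 (SE 0.14, adjusted p 0.381) and Hmgn5 at 0.26 (SE 0.10, adjusted p 0.455). None passed over all probe sets and 4 were higher adjusted over the list alone. The camera test gave adjusted p = 0.000638, and adjusted p = 0.0876 with an estimated correlation. Of 19 genes of endoplasmic reticulum stress 18 had negative differences, median -0.23, with 0 called and 2 lower adjusted over the list alone. With camera the list had adjusted p = 0.000174, and adjusted p = 0.599 with an estimated correlation. The liver tumour marker Afp differed by 0.10 (SE 0.28, adjusted p 0.950), and Cyp2e1, the main enzyme that activates DEN, by 0.03 (SE 0.10, adjusted p 0.949). The lists for DNA repair (34 measured, median 0.02, camera adjusted p = 0.646), p53 targets (20 measured, median -0.04, camera adjusted p = 0.953) and fetal liver and tumour markers (20 measured, median 0.08, camera adjusted p = 0.615) held 0 called members. Adjusted over the list alone, 1 p53 target was higher and 1 fetal or tumour marker lower.

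Across conditions, the directions of the genotype differences were compared by counts of genes, without a test of the counts. Of the 397 genes called at 4 weeks, 374 (94.2%) had the same sign with saline, at a median ratio of 0.390 to the 4-week change, and 165 (41.6%) had the same sign with DEN. The choice of these genes by their 4-week change itself favours a smaller ratio. The direct test of the difference with DEN against that with saline called 0 probe sets with limma, and 2170 at an unadjusted p under 0.05. Across 12896 genes, which are not independent replicates, the differences at 4 weeks correlated with those with saline at r = 0.353 and with those with DEN at r = -0.0819, and those with saline and DEN at r = -0.0133. Cyp7a1 was at -2.51 at 4 weeks and 0.63 with DEN, Id1 at 2.48 and 0.19, and Hmgcs1, an early enzyme of cholesterol synthesis, at -1.12 and 0.36. A test of the DEN difference against the 4-week difference, added after the data were seen, called 206 probe sets (100 up, 106 down), in 139 genes. In that test Cyp7a1 differed by 3.15 (SE 0.33, adjusted p 5.96e-05), Scara5 by -4.33 (SE 0.38, adjusted p 4.24e-06) and Id1 by -2.29 (SE 0.27, adjusted p 0.000309).

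**Figure D3:**
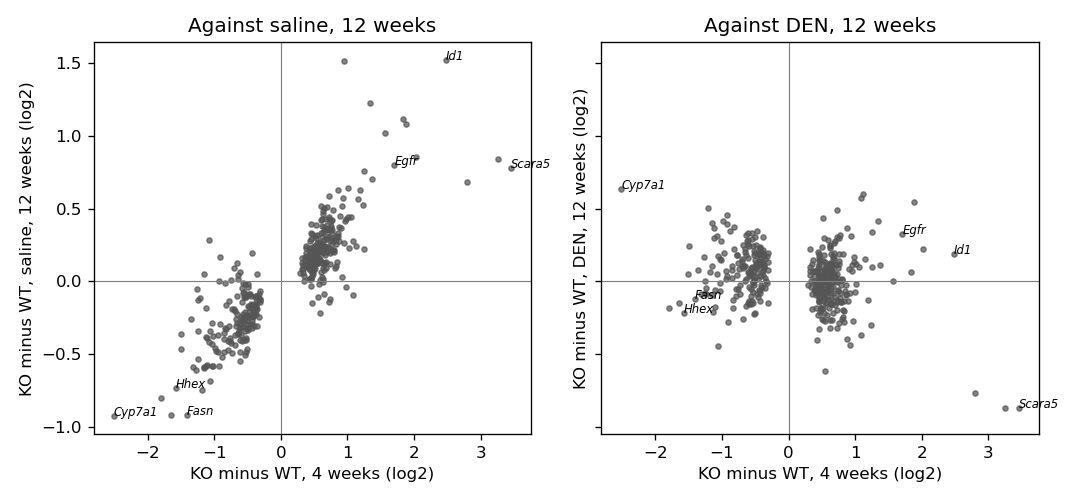
Knockout minus wild-type log2 differences of the 397 genes called at 4 weeks, 1 point per gene, with the difference at 4 weeks on the horizontal axis and that with saline (left) or DEN (right) at 12 weeks on the vertical axis. The sign was the same in 374 genes with saline and in 165 with DEN.

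Averaged over the 3 conditions, 224 probe sets differed between the genotypes (125 up, 99 down). Id1 rose by 1.40 (SE 0.11, adjusted p 7.44e-07), Egfr by 0.95 (SE 0.10) and Id3 by 0.73 (SE 0.07). Fasn fell by 0.81 (SE 0.10), Hhex by 0.84 (SE 0.10), and Aacs, which makes acetoacetyl-CoA for lipid synthesis, by 0.73 (SE 0.09, adjusted p 0.000151). Of 18 genes in each list, 6 of cholesterol synthesis fell (15 adjusted over the list alone), with Sqle at -0.56 (SE 0.10) and Lss at -0.49 (SE 0.09). With DEN alone, 12 of these 18 had positive differences and 6 negative, with a median of 0.14 and 0 called, also adjusted over the list alone (camera adjusted p = 0.212). Sqle was then at -0.07, Lss at -0.01 and Fdps at 0.40. In the same way 5 of fatty acid synthesis fell (11 adjusted over the list alone), with Gpam at -0.43 (SE 0.07) and Srebf1, a regulator of lipid synthesis, at -0.35 (SE 0.07). The lists had camera adjusted p = 3.68e-14 and 3.23e-08, and adjusted p = 0.316 and adjusted p = 0.351 with an estimated correlation. The DEN difference was small in several of these genes, at 0.19 for Id1, -0.12 for Fasn and -0.22 for Hhex. The direction was the same in all 3 conditions for 172 of the 224, which the choice of the 224 by their mean itself favours, and 19 had an unadjusted p under 0.05 in each. Among the 19 were Aacs (-1.06, -0.69 and -0.44 at 4 weeks, with saline and with DEN), Tpm1, a tropomyosin (-0.40, -0.37 and -0.38), and Hsd3b5 (0.70, 0.36 and 0.28). Centring the array medians gave 55 up and 95 down, and leaving out wild-type replicate 3 of saline gave 101 probe sets. The mean of 4 weeks and DEN alone gave 90 with all arrays in the fit (quantile 87), and 26 with the 6 saline arrays left out of the fit as well.

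The comparison of DEN with saline asks how the livers responded to the carcinogen. Over both genotypes 5497 probe sets changed (2265 up, 3232 down), and 4680 with quantile normalization (2146 up, 2534 down), of which 4008 were shared. The Gapdh ratio of 3' to 5' signal also moved with this comparison: it was 0.907 to 1.126 on the 6 DEN arrays and 1.187 to 1.408 on the 6 saline arrays, with no overlap. With that ratio as a covariate 3318 probe sets changed over both genotypes, 1755 in wild type and 2091 in knockout. Clock genes of opposite phase, the mean of Arntl, Npas2, Clock, Cry1 and Nfil3 minus that of Dbp, Tef, Per3, Nr1d1, Nr1d2 and Hlf, parted by -0.90 (SE 0.21, 95% interval -1.35 to -0.45). The hours of collection are not in the labels. Bcl6, a transcriptional repressor in growth hormone signalling, fell by 1.496 (SE 0.25, adjusted p 0.000184; quantile -1.46), the nuclear RNA Malat1 by 1.66 (SE 0.20; quantile -1.85), and the inducible heat shock gene Hspa1b by 1.28 (SE 0.31; quantile -1.31). Ezr, which links membrane and actin, fell by 1.73 (SE 0.17; quantile -1.68), and Mup3, a urinary protein gene of male liver, rose by 1.64 (SE 0.11; quantile 0.76). Ezr and Mup3 had moved the other way from 4 weeks to saline in wild type, by 2.20 (SE 0.24; quantile 2.12) and -1.84 (SE 0.15; quantile -0.998), so that saline arrays differed from both others.

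Many rises after DEN were in abundant liver transcripts and shrank on equal distributions. All 15 measured hepatocyte genes rose, with a median of 0.99 (camera adjusted p = 4.48e-28, and adjusted p = 0.0436 with an estimated correlation), but with quantile normalization the median was 0.01, with 3 up and 2 down (camera adjusted p = 0.965). Alb, serum albumin, rose by 1.33 (SE 0.06; quantile 0.12), and Cyp2e1 by 1.19 (SE 0.07; quantile 0.15). Ttr rose by 1.25 (SE 0.07; quantile 0.06, adjusted p 0.304), and Fabp1, a fatty acid binding protein, by 1.21 (SE 0.06), but was at -0.13 in quantile values. The same gap appeared at the top 1 percent of signal, 271 probe sets. The median was 0.70 higher with DEN than with saline, 0.68 higher at 4 weeks than with saline, and 0.03 higher with DEN than at 4 weeks. Oxidative phosphorylation (19 of 24 up, median 0.33; quantile 2 up, 4 down), ribosomal proteins (12 of 13 up, median 0.51; quantile 5 up, 0 down), and cytochrome P450 enzymes (19 up and 3 down of 34, median 0.27; quantile 3 up, 5 down, median -0.10) followed it. Their camera adjusted p on quantile values was 0.960, 0.0564 and 0.299.

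Macrophage and Kupffer cell genes were higher after DEN in the mean of the genotypes on both scales: 5 of 18 rose and 0 fell (7 rose adjusted over the list alone), and 7 rose with quantile normalization. C1qc, a complement component, rose by 0.57 (SE 0.09, adjusted p 6.52e-05; quantile 0.62), Lyz2, lysozyme, by 0.46 (SE 0.12; quantile 0.49) and Timd4, a receptor of resident macrophages, by 0.55 (SE 0.16; quantile 0.64). Timd4 was at 0.46 (adjusted p 0.0525) without wild-type saline replicate 1. Camera gave adjusted p = 0.00120, and adjusted p = 0.384 with an estimated correlation. In wild type alone 1 of 18 rose (median 0.06, camera adjusted p = 0.282), and in knockout 7 (median 0.36, camera adjusted p = 4.68e-05, and adjusted p = 0.257 with an estimated correlation). Lyz2 was at 0.19 (adjusted p 0.591) in wild type and 0.73 (adjusted p 0.00382) in knockout. Of 29 neighbours of Hmgn1 on chromosome 16, 3 rose and 3 fell (quantile 3 and 2; camera adjusted p = 0.771), among them Morc3 at -1.06 (SE 0.09; quantile -1.02) and Cbr1 at 0.33 (SE 0.07; quantile 0.35). Morc3 had moved the other way from 4 weeks to saline in knockout, by 0.91 (SE 0.13, quantile 0.90), as Ezr had. The DNA repair list had 1 rise and 6 falls among 34 genes (quantile 2 and 3; camera adjusted p = 0.295), and the p53 target list 1 rise and 4 falls among 20 (quantile 1 and 2; camera adjusted p = 0.159).

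By genotype, 1766 probe sets changed after DEN in wild type (919 up, 847 down) and 4071 in knockout (1734 up, 2337 down). Quantile normalization gave 983 (400 up, 583 down) and 2952 (1390 up, 1562 down). Centred medians gave 502 up and 1259 down in wild type and 2304 up and 1194 down in knockout, where they moved the median over all probe sets from -0.09 to 0.02. In wild type Ip6k2, an inositol phosphate kinase, fell by 1.72 (SE 0.23; quantile -1.67) and Abtb2 by 1.30 (SE 0.21; quantile -1.24). In knockout Smad7 fell by 1.84 (SE 0.23; quantile -1.75), Bcl6 by 2.02 (SE 0.36; quantile -2.01) and Pkdcc, a secreted kinase, by 1.37 (SE 0.13; quantile -1.31), and C1qc rose by 0.63 (SE 0.12; quantile 0.68). On the knockout arrays Smad7 was at 7.10 to 7.51 at 4 weeks, 8.07 to 9.20 with saline and 6.58 to 6.85 with DEN. At this probe set, with a name in _x_at, the saline arrays thus lay above both other groups, which quantile normalization does not undo. The other Smad7 probe set had its larger genotype difference at 4 weeks (1.48, adjusted p 9.52e-06), against 0.80 with saline (adjusted p 0.0728). The peak with saline is therefore stated for the 1 probe set only. Of 25 interferon response genes 4 rose in knockout (also 4 with quantile values), with Psmb9, an immunoproteasome subunit, at 0.56 (SE 0.13; quantile 0.65). The call of Iigp1, at 0.43 (SE 0.08), was lost with quantile values (-0.08, adjusted p 0.517). Camera gave adjusted p = 0.0171, and adjusted p = 0.0563 with an estimated correlation (quantile adjusted p = 0.0316 and adjusted p = 0.168). Without wild-type saline replicate 2 the wild-type count was 957, and without knockout saline replicate 1 the knockout count was 2501.

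The difference of the DEN responses between the genotypes, tested itself, called 0 probe sets with limma, and 2170 at an unadjusted p under 0.05. The smallest p-values were those of Cmtm6 at -0.72 (SE 0.14, adjusted p 0.258), Ngfr (adjusted p 0.258), whose size is not given because its knockout values with DEN are near the floor, and Id1 at -1.33 (SE 0.27, adjusted p 0.282) downward. Upward they were Acot13 at 0.64 (SE 0.13, adjusted p 0.282), Cyp7a1 at 1.56 (SE 0.33, adjusted p 0.282) and Txnrd2 at 0.78 (SE 0.18, adjusted p 0.332), none of which passed. With quantile values the adjusted p was 0.083 for Cmtm6, 0.365 for Txnrd2 and 0.350 for the others. Across genes the responses of the genotypes correlated at r = 0.489 (quantile 0.443), and 95.7% of the 488 genes called in wild type with quantile values had the same sign in knockout. Both responses subtract saline arrays, which stood apart in both genotypes. An offset of these arrays at single genes would give such agreement without a shared response to DEN. Centring the array medians moved the median of this difference over all probe sets from -0.05 to 0.13.

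The comparison of saline at 12 weeks with 4 weeks concerns age together with the injection, the difference between arrays and any difference in the hour of collection, which is not in the labels. The same clock genes parted by -0.85 (SE 0.29, 95% interval -1.48 to -0.21) in wild type and by -0.36 (SE 0.29, 95% interval -0.996 to 0.27) in knockout. In wild type 2232 probe sets changed (1141 up, 1091 down; quantile 1424, 826 up and 598 down). Dbp, a clock-controlled transcription factor, rose by 2.76 (SE 0.42, adjusted p 0.000145; quantile 2.69), Scara5 by 2.08 (SE 0.27; quantile 1.99) and Spry4, a feedback inhibitor of growth factor signals, by 1.40 (SE 0.23; quantile 1.32). In knockout 2685 changed (1376 up, 1309 down; quantile 1945, 1058 up and 887 down; centred medians 664 up and 2054 down, with the median over all probe sets moved from 0.07 to -0.05). Cish, induced by growth hormone, rose by 1.48 (SE 0.26; quantile 1.42), and Lama5, a laminin chain, by 1.60 (SE 0.32; quantile 1.503). Alb fell by 1.33 (SE 0.09; quantile -0.13, adjusted p 0.109) in wild type and by 1.34 (SE 0.09; quantile -0.15, adjusted p 0.0612) in knockout. All 15 hepatocyte genes fell in knockout (14 in wild type), against 1 up and 1 down with quantile values in knockout. With quantile values camera called 0 of the 39 lists in either genotype. Without wild-type saline replicate 1 the wild-type count was 1265, and without knockout saline replicate 2 the knockout count was 1502.

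The change from 4 to 12 weeks differed between genotypes at 1 probe set, that of Scara5, by -2.68 (SE 0.38, adjusted p 0.0140; quantile -2.62), with 1086 at an unadjusted p under 0.05. Scara5 rose by 2.08 in wild type between these ages. The call was lost with 64 added in place of 16 and in 9 of 12 fits without 1 array (-2.57, adjusted p 0.0938 without wild-type saline replicate 3), and the other tested probe set of Scara5 gave 0.61 (SE 0.37, adjusted p 0.999).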

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

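The tests of abundant transcripts, of the separate run of the saline arrays, of degraded RNA and of the shared sign were chosen after the results were seen, as was the comparison of the genotype effect with DEN against that at 4 weeks; the tests of a compressed range and of time of day and the other splits of the arrays were set before.

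Transcripts in the top 1 percent of signal were lower on the 6 saline arrays, and a rise after DEN as the whole cause is argued against by a median of 0.033 between DEN and 4-week arrays, against 0.70 between DEN and saline. A fall with age together with a rise after DEN would give the same 0.033 and stays open; that value had first served to test a fall with age alone, later left out for a separate run. The hybridization controls, which do not come from liver, were lower on the saline arrays by a mean of -2.56, as a separate run may give, and the batch and the saline group cannot be told apart. A compressed signal range stays open: the distance between CreX and BioB was 0.17 longer (SE 0.03) on the saline arrays. That first read as excluding it, since CreX was 2.83 times the 99th percentile on the other arrays, but on the saline arrays it was 0.672 of it, below the range in question, and judging on those arrays was decided after the result.

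On the knockout arrays at 4 weeks Id1, Id3 and Smad7 were higher and sterol synthesis genes lower. Degraded RNA on wild-type replicate 2 is argued against, since the sterol median was -0.79 without that array and -0.84 with it. A different time of day at collection cannot be told apart. Clock genes of opposite phase parted by -0.30 (SE 0.29, 95% interval -0.93 to 0.33), an interval that holds both 0 and a shift of the size sought. This SE pools the spread of all 6 groups, and the 4-week groups varied least (SD 0.0741 and 0.146, against 0.356 or more in the others). Their arrays did not overlap, at 0.33 to 0.48 in wild type and -0.0036 to 0.27 in knockout, so the interval does not make such a shift less likely. A genotype difference in livers without DEN stays open. Of the genes called at 4 weeks, 94.2% had the same sign on the saline arrays, against 41.6% with DEN, so the 4-week directions recurred with saline. Any other difference between the lines that recurs would give the same shared sign, so it cannot decide this. The direct test of the DEN difference against the saline difference called 0 probe sets. Other differences between the separately bred lines were not tested.

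Some gene lists moved differently after DEN in the 2 genotypes, by camera on the difference of the responses (knockout minus wild type), with 0 members called in any of them by limma and 2170 probe sets at an unadjusted p under 0.05. The medians were 0.46 for the HMG family (adjusted p = 0.305 with an estimated correlation), 0.12 for glutathione and NRF2 targets (0.726), 0.50 for cholesterol synthesis (0.619), 0.16 for fatty acid synthesis (0.755), -0.22 for endoplasmic reticulum stress (0.755), 0.28 for macrophages and Kupffer cells (0.755) and 0.089 for oxidative phosphorylation (0.755).

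The change from 4 to 12 weeks differed between genotypes for Scara5, by -2.68 in log2. It also differed by camera for lists without called members. The medians were -0.18 for immediate early genes, -0.20 for male-biased genes, 0.34 for cholesterol synthesis, 0.13 for fatty acid synthesis, -0.36 for the circadian clock, -0.14 for acute phase and inflammation, -0.31 for endoplasmic reticulum stress, 0.29 for matrix and stellate cells and 0.26 for macrophages and Kupffer cells. None of these lists was called with an estimated correlation, where the smallest adjusted p was 0.262, for the clock.

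The genotype effect with DEN differed from that at 4 weeks at 206 probe sets. Of 100 splits of the arrays 5 gave as many, the real one among them, with 412 as the highest other. The splits were drawn separately within each condition, so some can keep or mirror the genotypes at 4 weeks, which alone gave 611 calls. Their share is therefore no clean chance level, and chance is not excluded.

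For the contrasts of 3 arrays against 3, 10 splits are too few for a share under 0.05. The real count and the highest other were 611 and 1 for genotype at 4 weeks, 3 and 0 with saline, 2 and 45 with DEN, 1766 and 1 for DEN against saline in wild type, 4071 and 1 in knockout, 2232 and 1 for saline against 4 weeks in wild type, and 2685 and 0 in knockout. With DEN, 5 of the 10 splits gave at least 2 calls, and the split with 45 points to a structure of the samples, which was neither identified nor tested; in each of the other 6 contrasts only the real split, 1 of 10, reached its count. Of 100 splits, only the real one reached its count for the mean genotype effect (224, highest other 81) and for the mean DEN effect (5497, highest other 2711). Chance is thus unlikely for both, if the arrays are separate samples, but not excluded. For DEN the splits cannot part the carcinogen from the difference between the saline arrays and the others. For the difference of the change from 4 to 12 weeks 15 of 100 splits gave as many as the real count of 1 (highest other 670). This share also met the rule for chance set before. Splits that keep or mirror the genotypes at 4 weeks carry that effect, so this share is no clean chance level and chance is not excluded. For the difference of the DEN responses the real count was 0, so all 100 splits gave at least as many (highest other 18), which says nothing about chance. For the change from 4 to 12 weeks, the split with 670 mirrors the genotypes at 4 weeks, which adds both genotype effects.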

How the results depend on the processing

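Cyclic loess, the Gapdh covariate, and leaving out the high-Gapdh or the saline arrays were chosen after the data were seen. All alternatives set before the data were seen were run. A filter or the removal of probe sets gave no value for genes it removed. Fewer tested probe sets, arrays or groups are the construction of some alternatives; for all other changed results the cause was not tested. An array's signal over background limits low transcripts.

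Counts that moved by over 1.5 times were, for genotype at 4 weeks (611), 367 with centred medians, 269 without trend, 1000 with array weights, 180 without the high-Gapdh arrays and 255 without the saline arrays. For genotype with saline (3) they were 6 with quantile normalization, 9 with centring, 1 without trend, 94 with weights, 1 without _x_at and _s_at probe sets and 9 with only the compared groups. For genotype with DEN (2) they were 1 with centring, no filter or the Gapdh covariate, and 0 by limma with the 60th percentile filter (1634 at an unadjusted p under 0.05), weights (1402), only the compared groups (1334) or no saline arrays (1642). For the mean genotype effect (224) they were 58 without trend, 338 with the Gapdh covariate, 141 without the high-Gapdh arrays and 26 without the saline arrays. DEN against saline gave 983 (quantile), 1160 (no trend) and 1157 (cyclic loess) in wild type, 2091 in knockout and 3318 in the mean with the Gapdh covariate, and 1 for the difference of the responses without _x_at and _s_at probe sets. Saline against 4 weeks gave 1424 (quantile) and 4077 (weights) in wild type and 4185 (weights) in knockout. The difference of these changes (1) was 4 with weights, 3 with only the compared groups, and 0 by limma with 64 added (1092), without trend (1114) and without the high-Gapdh arrays (1091). The correlation of the 4-week and saline effects (0.353) was 0.252 with 1 added, 0.482 with 64 added and 0.506 with the 60th percentile filter.

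With a replicate block the counts were 541, 3, 2, 220, 1700, 3954, 5395, 0, 2164, 2588 and 1, in the order of the ranges below, all within 1.5 times. Replicate numbers did not pair the arrays (mean r of same numbers -0.00205).

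Leaving out each array in turn gave 269 to 591 for genotype at 4 weeks, 0 to 6 with saline, 0 to 4 with DEN and 101 to 298 in the mean. It gave 957 to 1870 for DEN against saline in wild type, 2501 to 3433 in knockout, 4403 to 5415 in the mean and 0 to 2 for the difference. It gave 1265 to 2249 for saline against 4 weeks in wild type, 1502 to 2195 in knockout and 0 to 1 for the difference. Correlations were 0.302 to 0.371 (4 weeks with saline), -0.117 to -0.0412 (4 weeks with DEN) and -0.0601 to 0.0341 (saline with DEN). Uncalled genes that changed sign were Hmgn1 (-0.13 to 0.062 at 4 weeks, -0.071 to 0.0094 with saline, -0.095 to 0.091 with DEN, -0.058 to 0.012 in the mean), Afp with DEN (-0.15 to 0.44) and Cyp2e1 (-0.090 to 0.12 with saline, -0.043 to 0.095 with DEN).

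With quantile normalization, signs reversed for Hmgn1 (0.011 at 4 weeks, -0.036 with DEN) and, in DEN against saline, for Fabp1 (-0.23 in wild type, -0.024 in knockout, -0.13 in the mean), Serpina1c (-0.0100) and Fgb (-0.097) in wild type and Iigp1 (-0.084) in knockout. List medians reversed for P450 enzymes (-0.094 in wild type, -0.12 in knockout, -0.10 in the mean), gluconeogenesis (-0.013, 0.031, -0.010), bile acids (0.0097, 0.014, -0.058), oxidative phosphorylation in wild type (-0.022) and glutathione in the mean (0.017). Against 4 weeks they reversed in wild type for P450 enzymes (0.048), male-biased genes (0.051), acute phase (0.15) and oxidative phosphorylation (0.012), and in knockout for fatty acid synthesis (0.0088) and oxidative phosphorylation (0.021). Cyclic loess reversed Hmgn1 (0.00033 at 4 weeks, 0.0082 with saline, -0.016 with DEN), bile acids (-0.017 in knockout, 0.00072 in the mean), glutathione (0.018), acute phase in wild type (0.035) and oxidative phosphorylation in knockout (0.030). Centring reversed Cyp2e1 with saline (-0.11), weights Hmgn1 with DEN (-0.0032), and leaving out the high-Gapdh arrays Hmgn1 at 4 weeks (0.042) and in the mean (0.0054).

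Of 212 called gene values in the narrowed set, quantile normalization kept 173, lost 33 and reversed 6, cyclic loess kept 203, no trend 164 and the Gapdh covariate 191. Of 514 under the original rule, quantile normalization kept 270, lost 177 and reversed 67, and cyclic loess kept 390, lost 117 and reversed 7. Of 121 list calls, 25 held with an estimated correlation, 41 with quantile normalization and 67 with cyclic loess.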

Other observations

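The comparison of DEN with the 4-week arrays, and the search for changes shared by both comparators, were chosen after the data were seen. DEN and 4-week arrays also differ in age and in the clock genes given below. Their Gapdh ratio of 3' to 5' signal was 0.907 to 1.126 with DEN and 1.125 to 2.19 at 4 weeks. This comparison was not fitted with that ratio as a covariate. Interferon response genes were higher with DEN than at 4 weeks: 10 of 25 rose and 0 fell (15 higher and 1 lower adjusted over the list alone), with a median of 0.31. Camera gave adjusted p = 2.39e-07, and adjusted p = 0.00119 with an estimated correlation; with quantile normalization 10 rose (adjusted p = 0.00100 with an estimated correlation). Of 18 macrophage and Kupffer cell genes 9 rose and 0 fell, with a median of 0.31 (camera adjusted p = 1.04e-05, and adjusted p = 0.674 with an estimated correlation). Cholesterol synthesis fell in wild type from 4 weeks to DEN, at 10 of 18 genes (median -0.55, camera adjusted p = 4.71e-11, and adjusted p = 0.272 with an estimated correlation), while in knockout 4 rose and 0 fell (median 0.21, camera adjusted p = 0.0133, and adjusted p = 0.898 with an estimated correlation).

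With quantile normalization, 1383 of the 4680 probe sets that changed between DEN and saline also changed in the same direction against 4 weeks (598 up, 785 down). Both comparisons use the same DEN arrays, and over probe sets they correlated at 0.497, as in 20 simulations without an effect (0.498), so the correlation shows no shared change. These simulations gave 0 shared calls, but almost nothing is called without an effect, so 0 is no chance level for the overlap. By the smaller of the 2 values, Nr4a3 (1.20 against saline and 1.09 against 4 weeks) and Dbp (0.94 and 2.68) led the rises. Further down the order, the acute phase gene Saa2 rose by 0.74 against saline and 0.85 against 4 weeks, and Alas1, the first enzyme of heme synthesis, by 0.73 and 1.07. Bcl6 was at -1.46 and -1.65, Hspa1b at -1.31 and -1.25, and the clock gene Npas2 at -1.01 and -1.30.

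Clock genes of opposite phase differed between conditions. The mean of the first set minus the second was 0.41 ± 0.0741 (SD, n = 3) in wild type and 0.10 ± 0.146 (SD, n = 3) in knockout at 4 weeks, -0.44 ± 0.356 and -0.26 ± 0.361 with saline, and -1.48 ± 0.360 and -1.02 ± 0.589 with DEN. The mean difference between DEN and saline was -0.90 (SE 0.21, 95% interval -1.35 to -0.45). The hours of collection are not in the labels.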
